A study of Mus musculus with 3 samples.

How the data were processed

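The series holds 3 RNA-seq libraries of RAW264.7, a mouse macrophage cell line derived from a virus-induced tumour. One library came from untreated cells, 1 from cells given lipopolysaccharide (LPS, a bacterial outer-membrane glycolipid that activates toll-like receptor 4) at 0.5 µg/ml for 6 h, and 1 from cells that received harmine at 10 µM, 0.5 h ahead of the same LPS exposure. Harmine is a plant beta-carboline alkaloid known to inhibit the kinase DYRK1A and monoamine oxidase A. Per the labels, RNA was poly(A)-selected, made into libraries in which the second strand was marked with dUTP, and sequenced as pairs of 150-base reads; the labels also give lung as the tissue of this cell line. Each group holds 1 library, so no difference has a replicate check and no p-values were computed. The values compare these 3 libraries, and variation between cultures is part of every difference. No library came from cells given harmine without LPS. An effect of harmine on the LPS response therefore cannot be told apart from an effect that does not depend on LPS.

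The deposited gene table gives for each library an FPKM value (fragments scaled by transcript length and library size), per the file headers. It also gives an estimated count per gene, per the file headers, deposited without normalization. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the mouse build mm10; what each tool was used for, and any filter on genes, is not given in the sources used here. The ratio of deposited count to FPKM was the same between libraries up to 1 factor: over 12036 genes with more than 50 counts in each library, the log2 ratio of LPS to control varied with an SD of 0.00583. The deposited counts did not behave as counts of single reads. In every library more genes had a count of exactly 4 than of 3 (1072 against 566 in control, 1096 against 573 with LPS, 994 against 619 with harmine plus LPS), so 4 deposited counts were taken as 1 read pair wherever counting error was computed. FPKM, not counts, was the main measure, as set in advance, and no count model was fitted, since each group holds 1 library.

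Genes with at least 1 FPKM in at least 1 library were compared, 12197 of the 26661 in the table. The difference between libraries was log2(FPKM + 1) in one minus that in the other, which understates the difference of genes with low values; folds given as such are plain FPKM ratios. A gene was counted as higher or lower at 2-fold or more on the log2(FPKM + 1) scale. Beside chosen FPKM ratios stands a 95% exact interval from the binomial split of read pairs between the libraries; it covers counting error only. Against a count of 0, the ratio was computed against a floor of 3 read pairs (12 deposited counts) in the library at 0, and is a bound at that floor; it is not the lower limit of the 95% interval, which lies further down (221 where the floor gives 273 for Il6, LPS over control). Reads of near-identical genes (the Bcl2a1 family, Hspa1a and Hspa1b, Lyz1 and Lyz2, globins, histones) and of overlapping genes could be split between them, so their single values are uncertain, as is that of Ighj1, a segment shorter than a read.

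Fixed before the data were examined were the groups, the 3 comparisons, the filter, the thresholds, the alternatives named below as set in advance, the 37 gene lists and the rule for named genes. That rule takes, per comparison, the 10 named genes with the highest and the 10 with the lowest log2 difference among genes with at least 10 FPKM in 1 of the libraries compared; for each list described, up to 4 members with the largest absolute difference; for reversal, the 10 genes with the largest smaller-of-both differences in opposite directions; and always Maoa, Dyrk1a, Tnf, Il6, Il1b, Nos2 and Ptgs2. The 10 genes for reversal were taken among genes with at least 10 FPKM in the LPS library. Predicted genes, pseudogenes, mitochondrial genes and small RNA genes were left out of the named genes. For each list with at least 5 members at 1 FPKM, the median log2 difference was placed among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. The percentile describes these libraries and is not a test over replicates. Reversal counted, among genes 2-fold or more higher or lower with LPS, those 1.5-fold or more the other way in harmine plus LPS against LPS. Because both differences contain the same LPS library, 100 sets of libraries with no harmine effect were simulated, with noise from the robust spread of harmine plus LPS against LPS at each expression level. The noise was drawn independently for each gene, so deviations shared by many genes of a library were not simulated. Gene positions are those of the deposited table, on mm10 per the submitters' processing notes; 26595 gene identifiers were found in the GENCODE M21 annotation, 26454 of them with the same start.

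The alternatives set in advance were pseudocounts of 0.1 and 5 FPKM, no filter, a filter at 5 FPKM, rescaling by the median of ratios, to TPM or by the upper quartile, named genes only, 1.5-fold and 4-fold thresholds, and for reversal a 4-fold LPS difference and a 2-fold difference the other way. Chosen after seeing the data were the 4 counts per read pair, the counting intervals, the counts limited by them, the counts without other-tissue markers, the matching of older symbols in the lists, the 10 other-tissue marker lists, the scan of 199 KEGG pathways (from the deposited annotation, at least 15 compared members, 2000 random lists each) and most tests of explanations.

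The functions were tested on data simulated for LPS against control, with 11741 genes past the filter and 4 sets of 50 genes changed by known folds. At the 2-fold threshold they recovered 50 of 50 genes lowered to 0.25, 44 of 50 lowered to 0.4, 49 of 50 raised 2.5-fold and 50 of 50 raised 4-fold, and called 91 genes that had not been changed. The list raised 2.5-fold lay at percentile 100, and 5 of 100 unchanged lists lay outside the middle 95%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.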

Results

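Gene expression was measured by poly(A) RNA-seq in RAW264.7 macrophages left untreated, given LPS, or given harmine and then LPS, with 1 library each. The deposited counts summed to 58169999 in control, 52845589 with LPS and 56391972 with harmine plus LPS, with 4 counts taken as 1 read pair. Counts above 0 were found for 21809, 22933 and 23812 genes, and at least 1 FPKM for 11302, 11126 and 11454. The 10 genes with the most counts held 5.88%, 6.26% and 5.81% of the counts, and mitochondrial transcripts 3.80%, 3.18% and 4.06%. Where 3 FPKM values follow a gene below, they are control, LPS and harmine plus LPS in that order, and the range in brackets after a fold is its 95% counting interval. No difference has a replicate check, so all values compare these 3 libraries.

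The first comparison asked what 6 h of LPS did to the macrophages. The LPS library held far more transcript of secreted inflammatory mediators: Il1b, encoding interleukin 1 beta, stood at 0.836 FPKM in control and 484 FPKM with LPS, 579.8-fold (389 to 860.0) higher, and Csf3, a granulocyte growth factor, was 490.5-fold (323 to 764) higher. Interferon-stimulated genes, surface receptors and feedback inhibitors of NF-kB were higher as well. Genes of DNA replication and mitosis were lower: 19 of 28 compared members of the replication and G1/S list stood 2-fold or more below control, and no member stood 2-fold above. Across the 12197 genes, 706 were 2-fold or more higher and 880 lower, and 225 and 86 at 4-fold; the median difference of all genes was -0.13 log2.

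Among inflammatory cytokines, 15 of 18 compared members were 2-fold or more higher with LPS and none lower (median 3.39 log2, percentile 100 of matched random lists). Besides Il1b (chromosome 2, 129364570 to 129371139) and Csf3 (chromosome 11, 98701263 to 98703629), Il1a was higher by 6.57 log2, from 0.312 to 123 FPKM, and Lif, a cytokine of the interleukin 6 family, by 5.66 log2. Il6 had no counts in control and 20.4 FPKM with LPS, at least 273-fold higher against the floor of 3 read pairs, and Tnf, already at 55.6 FPKM in control, reached 1436 FPKM, 25.9-fold (24.5 to 27.2) higher. Of 16 chemokines, 13 were 2-fold or more higher and 1 lower. Ccl3 became one of the most abundant transcripts, at 89.8 FPKM in control and 8466 FPKM with LPS. Cxcl2 (chromosome 5, 90903871 to 90905938), a neutrophil attractant, was 315-fold (259 to 381) higher, Ccl5 309.6-fold (198 to 529.9), and Ccl22 and Ccl2 differed by 6.65 and 6.26 log2.

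The interferon response list had 41 of 43 members 2-fold or more higher and none lower (median 3.15 log2, percentile 100). Isg15, a ubiquitin-like modifier, stood at 2.09 and 219 FPKM, Usp18, which removes it, at 1.62 and 88.6 FPKM, and the transcription factor Irf7 at 2.25 and 70.2 FPKM. Rsad2, encoding the antiviral enzyme viperin, differed by 4.60 log2. Among enzymes of nitric oxide, prostaglandin and itaconate synthesis, 7 of 14 were 2-fold or more higher and 3 lower. Acod1 (chromosome 14, 103046977 to 103056573), which makes itaconate, was 261-fold (231 to 296) higher, the inducible cyclooxygenase Ptgs2 168-fold (146 to 194) and the inducible nitric oxide synthase Nos2 33.1-fold (26.2 to 42.6). Ptgs1, the constitutive cyclooxygenase, was 13.4-fold (10.5 to 17.0) lower.

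Of the 21 NF-kB feedback and surface targets, 19 were 2-fold or more higher and none lower (median 2.64 log2). Examples were the costimulatory receptor Cd40 at 1.10 and 98.6 FPKM, Nfkbiz, which differed by 4.81 log2, and Traf1, by 4.08 log2. Immediate early genes and feedback phosphatases of MAP kinases had 15 of 22 members higher and none lower, led by Dusp5 (4.11 log2), Myc (3.88) and Dusp2 (3.86). Suppressors of cytokine signalling had 6 of 14 members higher and 1 lower; Socs3 differed by 4.45 log2 and Zfp36l2, an RNA-binding protein that promotes mRNA decay, by -2.23. Costimulation and checkpoint genes had 6 of 7 members higher. Components of toll-like receptor 4 signalling had 4 of 24 higher and none lower, among them the coreceptor Cd14 at 231 and 813 FPKM. Other pattern recognition receptors had 5 of 14 higher, led by Clec4e (2.32 log2), and 1 lower, Tlr13, a sensor of bacterial ribosomal RNA (-2.07 log2). Inflammasome and pyroptosis genes had 4 of 14 higher, including Nlrp3 at 17.0 and 177 FPKM, and 1 lower, Txnip (-1.38 log2).

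In the lower direction, the replication and G1/S list had a median of -1.20 log2 (percentile 0). The transcription factor E2f2 differed by -2.55 log2, the replication proteins Gins1 and Mcm7 by -1.96 and -1.77, and Ccnd1, encoding cyclin D1, by -1.60. The G2/M and mitosis list had 11 of 26 members lower and none higher, with the proliferation marker Mki67 at 84.5 and 30.8 FPKM and Ccna2 at 65.9 and 22.4 FPKM. Thymidine kinase, encoded by Tk1 (chromosome 11, 117815526 to 117826092), was 12.6-fold (10.8 to 14.6) lower. Kbtbd11 (chromosome 8, 15011025 to 15033333) had the lowest difference of the named genes, -3.95 log2, from 37.5 FPKM in control, 25.3-fold (21.5 to 29.6) lower. Among the others were Plau, encoding urokinase (-3.06 log2), Gpr183, a receptor for oxysterols (-2.89), Ndrg2 (-2.88), Susd3 (-2.95), the Ras regulator Rasa3 (-2.87) and Nrm, a nuclear envelope protein (-2.74).

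Nuclear genes of oxidative phosphorylation were lower together but by less: none of 30 passed 2-fold, 9 were 1.5-fold or more lower, and the median was -0.51 log2 (percentile 0), with Sdhb at 56.9 and 29.3 FPKM. Cholesterol genes had 6 of 23 members 2-fold or more lower and none higher, including Pmvk (-1.31 log2) and Fdps (-1.29), enzymes of the mevalonate pathway. Of the 15 LXR target and fatty acid synthesis genes, 5 were lower and none higher; the desaturase Scd2 stood at 237 and 32.6 FPKM and the sterol exporter Abcg1 at 10.3 and 1.76 FPKM. The 17 macrophage identity genes had a median of -0.33 log2, with Csf1r, the receptor for macrophage growth factor, at 259 and 65.8 FPKM, and Adgre1, encoding the F4/80 antigen, at 5.70 and 16.4 FPKM. Reference genes had a median of -0.13 log2, that of all genes.

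Markers of other tissues were present, and several stood higher in both LPS libraries than in control. Col1a1, a fibroblast collagen, was at 0.527, 3.37 and 3.45 FPKM, Col1a2 at 0.367, 1.86 and 2.12 FPKM, and the epithelial genes Krt8 and Epcam at 2.61, 8.09 and 10.5 FPKM and 0.995, 3.07 and 4.45 FPKM. The summed FPKM of intestinal markers was 55.7, 193.7 and 196.7, and that of keratinocyte markers 2.55, 12.3 and 15.8. The lung epithelium list had 2 of its 4 compared members 2-fold or more higher and a median of 0.81 log2, and the fibroblast and endothelial list 3 of 4 and 1.29. The former 4 were the epithelial genes Epcam, Cdh1, Krt8 and Krt18, and the lung markers Sftpb, Ager and Hopx stayed under 1 FPKM in every library. The latter 4 were Col1a1, Col1a2, Col3a1 and Acta2, and the endothelial genes Pecam1, Cdh5, Kdr, Vwf and Emcn stayed under 1 FPKM. Without the markers of other cell types, 678 genes were higher than control and 877 lower. Of the genes at 2-fold, 193 of the higher and 214 of the lower ones had under 5 FPKM in both libraries.

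**Figure D1:**
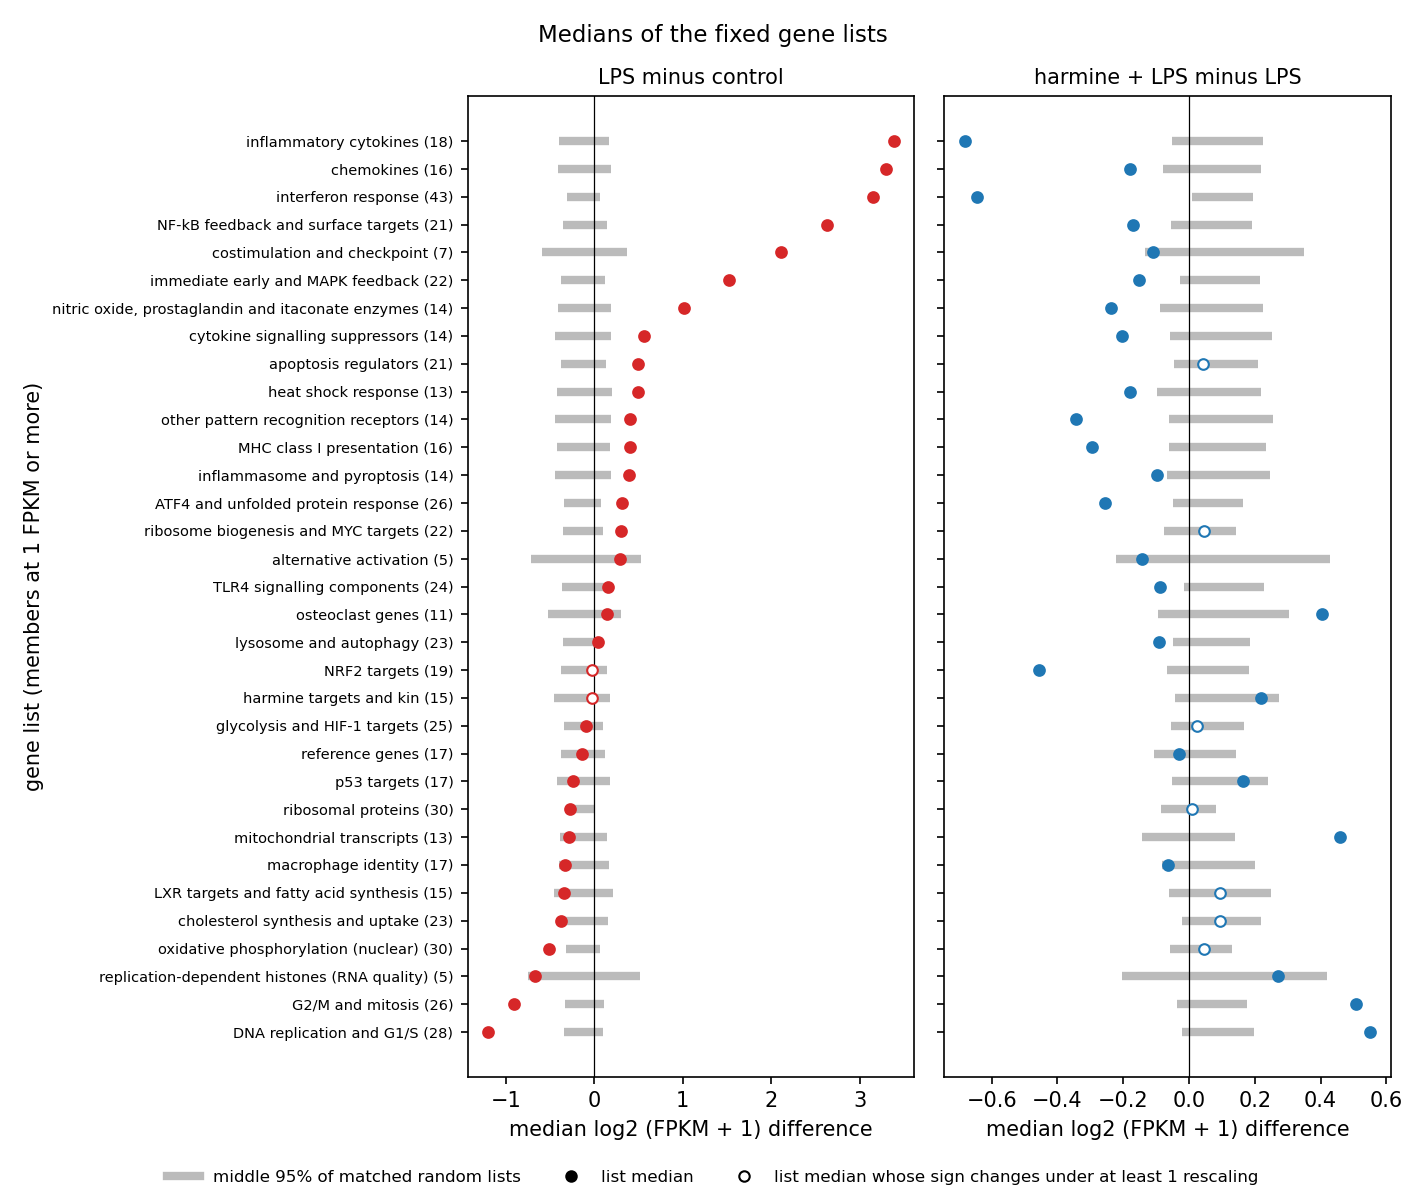
Median log2(FPKM + 1) difference of the 33 lists with at least 5 compared members, for LPS minus control and for harmine plus LPS minus LPS, each with the middle 95% of its matched random lists as a grey bar. The replication list lies lowest with LPS (-1.20) and highest with harmine (0.55); open symbols mark 2 medians with LPS and 7 with harmine whose sign changes under at least 1 rescaling.

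The second comparison asked what harmine changed when given ahead of LPS. Harmine plus LPS and LPS alone were much closer to each other than either was to control: 81 genes were 2-fold or more higher and 114 lower with harmine, and 98.4% of the compared genes lay within 2-fold. In the simulated test data, with counting error only, 91 unchanged genes of 11741 compared passed 2-fold. Part of the 81 and 114 may therefore be counting error. Of the 114 lower genes, 77 had stood 2-fold or more above control with LPS and 2 below it. Of the 81 higher genes, 28 had stood 2-fold or more below control with LPS and 5 above it. Both differences contain the LPS library, so chance in it adds to the 77 and the 28. Inflammatory mediators were lowered unevenly: Csf3 was 6.80-fold (6.45 to 7.18) lower and Il6 5.76-fold (4.77 to 6.92), while Tnf was 1.41-fold (1.39 to 1.44) lower. Nos2 and Ccl5 differed by -0.22 and -0.15 log2. Nfatc1, Rgs16 and Bcl2l11 were among the genes 2-fold or more higher. Genes of DNA replication and mitosis, low with LPS, were higher by less, with 1 of 28 and 0 of 26 list members at 2-fold and 11 and 8 at 1.5-fold.

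Of the 18 inflammatory cytokines, 7 were 2-fold or more lower with harmine and 1 higher (median -0.68 log2, percentile 0). After Csf3 and Il6 came Il27, at 102 FPKM with LPS and 31.6 FPKM with harmine plus LPS, and the growth factor Csf2 at 66.8 and 21.8 FPKM. Il1b was 2.16-fold lower. Among 16 chemokines, 4 were lower and none higher: Cxcl3 at 6.16 and 0.395 FPKM, Cxcl2 4.50-fold (4.38 to 4.62) lower, and Ccl3 and Ccl2 by -1.07 and -1.06 log2. The interferon response list had 7 of 43 members lower at 2-fold and 25 at 1.5-fold, none higher (median -0.65 log2, percentile 0). Its examples were the nucleic acid sensor Zbp1 (-1.54 log2), Isg15 (-1.37), Ifit2 (-1.34) and Ifnb1, encoding interferon beta, at 6.05 FPKM with LPS and 1.76 FPKM with harmine plus LPS, from 273 and 85 deposited counts.

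C5ar1 (chromosome 7, 16246743 to 16259540), the receptor for complement fragment C5a, stood at 1.73, 33.7 and 4.87 FPKM, 6.91-fold (5.95 to 8.06) lower with harmine. Hdc, which makes histamine, differed by -1.85 log2, Acod1 was 3.29-fold (3.24 to 3.34) lower and Ptgs2 1.82-fold (1.79 to 1.86). Marcksl1 stood at 21.3, 465 and 143 FPKM, Slfn4 at 22.1, 203 and 63.0 FPKM and Ms4a6d at 5.78, 25.4 and 6.98 FPKM. Igsf6, an immunoglobulin family membrane protein, was at 28.9, 39.5 and 11.1 FPKM and so below control with harmine. Among enzymes of nitric oxide, prostaglandin and itaconate synthesis, 3 of 14 were lower, Acod1, the oxidase subunit Cybb (-1.50 log2) and Sod2 (-1.28), and 1 was higher, Ptgs1 (1.15). Inflammasome genes had 3 of 14 lower and none higher: Casp1 (-1.23 log2), Il1b and Nlrp3 (-1.09). Of other pattern recognition receptors, 2 of 14 were lower, Clec4e (-1.53 log2) and the scavenger receptor Msr1 (-1.18). None of the 21 NF-kB feedback and surface targets passed 2-fold either way, and 4 were 1.5-fold or more lower and 1 higher (median -0.17 log2, percentile 0.06, beside -0.18 and 0.14 for the chemokines), with Cd83 at 93.7 and 164 FPKM the highest and Ikbke at 30.8 and 17.1 FPKM the lowest. The toll-like receptor 4 list had 1 of 24 lower, Irak3 (-1.20 log2), and the suppressors of cytokine signalling 1 of 14, the same Irak3. Immediate early genes went both ways, with Egr2 (1.12 log2) higher and Egr1 (-1.02) and Maff (-1.01) lower.

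Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G protein signalling, stood at 0.134, 5.62 and 22.8 FPKM, 4.05-fold (3.47 to 4.75) higher with harmine than with LPS alone. Tmem26 was at 1.98, 4.21 and 14.9 FPKM, Fam133b at 5.42, 9.82 and 29.7 FPKM, and Tnfrsf23, a decoy receptor for the death ligand TRAIL, at 5.23, 4.55 and 14.4 FPKM. Bcl2l11, encoding the pro-apoptotic protein BIM, was 2.53-fold (2.39 to 2.68) higher. Id1 differed by 1.35 log2, the collagen Col5a3 by 1.30, the betaine transporter Slc6a12 by 1.29 and the anion transporter Slco4a1 by 1.22. Nfatc1 (chromosome 18, 80606205 to 80713071), a transcription factor whose nuclear export DYRK1A promotes, was at 17.7, 7.14 and 20.6 FPKM, 2.89-fold (2.67 to 3.13) higher. The transcripts of harmine's known targets differed less: Dyrk1a, at 8.01 FPKM in control, by 0.30 log2 between harmine plus LPS and LPS, and Maoa, at 7.81 FPKM, by -0.08. In the list of harmine targets and kin, 1 of 15 members was 2-fold or more higher, Nfatc1, and none lower; Dyrk3 (0.81 log2) and the splicing kinases Clk3 (0.52) and Clk4 (0.45) came next. The osteoclast list had a median of 0.40 log2 (percentile 99.8), with 4 of 11 members 1.5-fold or more higher, Nfatc1 among them, and 2 lower, including Mmp9 (-0.92).

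The replication and G1/S list had a median of 0.55 log2 (percentile 100), with 11 of 28 members 1.5-fold or more higher and none lower; Mcm7 stood at 56.2, 15.8 and 33.1 FPKM and Gins1 at 19.7, 4.30 and 8.98 FPKM. The G2/M and mitosis list was similar (median 0.51 log2, 8 of 26 higher at 1.5-fold), with Mki67 at 84.5, 30.8 and 57.8 FPKM and Aurkb at 45.4, 16.3 and 29.7 FPKM. Transcripts encoded by mitochondrial DNA had a median of 0.46 log2 (percentile 100), with 1 of 13 at 1.5-fold or more and none at 2-fold; the highest were mt-Nd6 (0.61 log2) and mt-Nd2 (0.57). Antioxidant NRF2 targets were lower: 9 of 19 at 1.5-fold, none higher, with a median of -0.46 log2 (percentile 0). The heme oxygenase Hmox1 stood at 36.7, 82.8 and 40.1 FPKM, Me1 at 5.80, 7.70 and 3.56 FPKM and the ferritin light chain Ftl1 at 1828, 1801 and 1104 FPKM. Of the 26 ATF4 and unfolded protein response genes, 3 were 2-fold or more lower and none higher (median -0.26 log2): Xbp1, the chaperone Hspa5 at 330.1, 487 and 240.2 FPKM, and Dnajb9. Macrophage identity genes had a median of -0.06 log2, with Fcgr1 (-1.15) and Lyz2 (-0.89) lowest. Reference genes had a median of -0.03 log2, and Actb differed most, at 1030.4, 1171 and 675 FPKM.

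**Figure D2:**
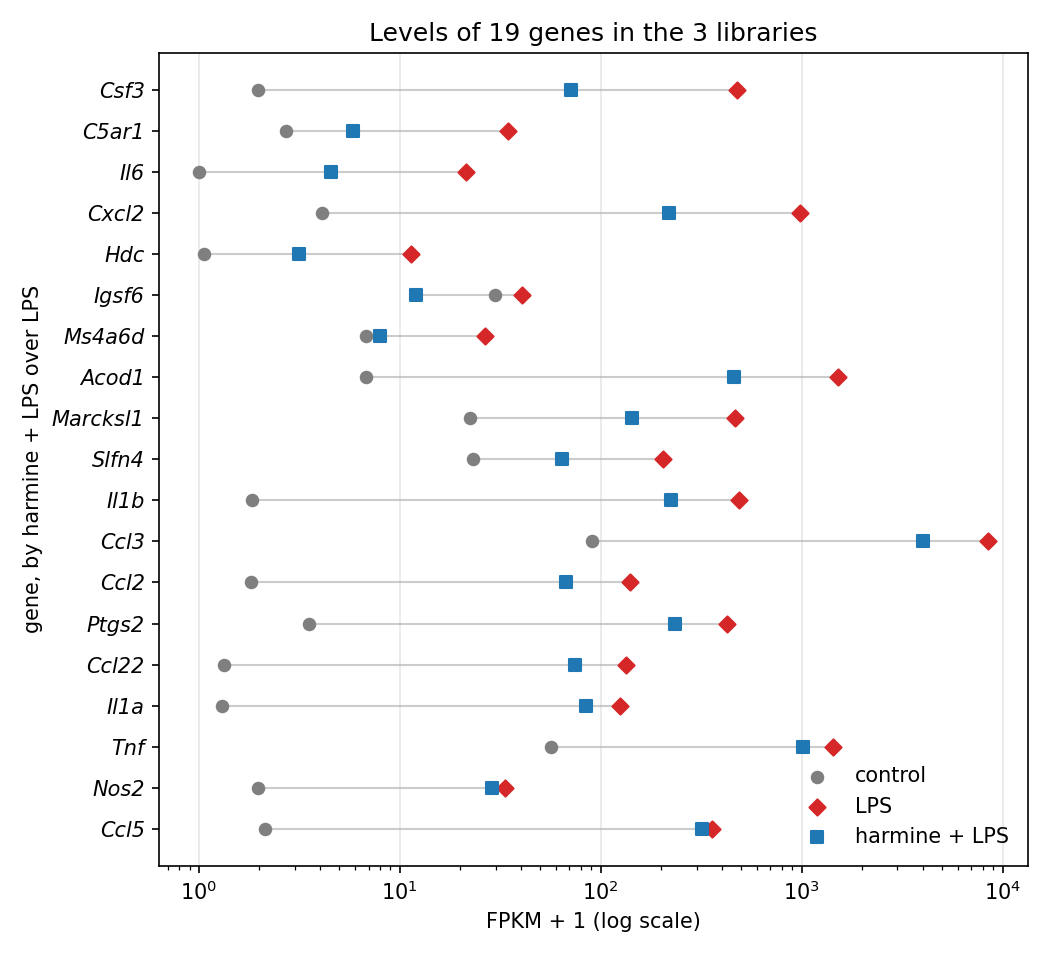
FPKM + 1 on a log axis for 19 genes, ordered by their difference between harmine plus LPS and LPS, with 1 symbol for each of the 3 libraries and a line over their range. Csf3 stood at 0.971, 476 and 70.0 FPKM in control, LPS and harmine plus LPS, whereas Ccl5 differed little between the LPS libraries (355 and 319 FPKM).

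The balance of higher and lower genes depended on the scaling between libraries, the pseudocount and the threshold. The median of all genes was 0.10 log2 as deposited and -0.02 after median-of-ratios rescaling, and higher genes made up 41.5% of the calls as deposited, 25% after median-of-ratios rescaling and 34.8% after upper-quartile rescaling. TPM rescaling left the median at 0.10 log2 but enlarged all values beside the fixed pseudocount and filter, and gave 57.6%; a pseudocount of 0.1 FPKM gave 60.8%. At a 1.5-fold threshold 646 genes were higher and 408 lower, 61.3% of the calls being higher. Of the 8415 genes that LPS moved by less than 1.5-fold, 33 were 2-fold or more higher and 22 lower with harmine.

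The third question was how far the LPS differences stood back towards control in the harmine plus LPS library. Of the 706 genes 2-fold or more higher with LPS, 200 (28.3%) were 1.5-fold or more lower with harmine plus LPS than with LPS, 28 were higher and 478 neither. Simulated libraries without a harmine effect, which share the chance deviations of the LPS library, gave a median of 19 lower (range 9 to 33) and 6 higher (0 to 13). Of the 880 genes lower with LPS, 193 (21.9%) were higher with harmine, 11 lower and 676 neither, against simulated medians of 31.5 (17 to 49) and 6.5 (1 to 16). The median gene kept most of its LPS difference: the recovered share was 14.3% for higher genes and 22.6% for lower genes, beside 2.88% and 5.52% in simulation. After median-of-ratios rescaling this order turned, to 21.3% and 15.6%, with 273 higher genes lower with harmine and 110 lower genes higher. Among genes with at least 10 FPKM with LPS, the 10 with the strongest opposite differences were all higher with LPS. That filter left out genes that LPS lowered to under 10 FPKM, such as Ptgs1 at 17.5, 1.31 and 4.13 FPKM. The added 1 FPKM also shrinks differences of low values. The 10 genes were Csf3, C5ar1, Il6, Cxcl2, Hdc, Ms4a6d, Acod1, Marcksl1, Slfn4 and Il27. Ms4a6d came nearest to control, at 0.23 log2 above it, and Acod1 and Csf3 still stood 6.08 and 5.17 log2 above. Across genes, which are not independent replicates, the covariance of the LPS and harmine differences was -0.122, and -0.0340 in simulation.

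**Figure D3:**
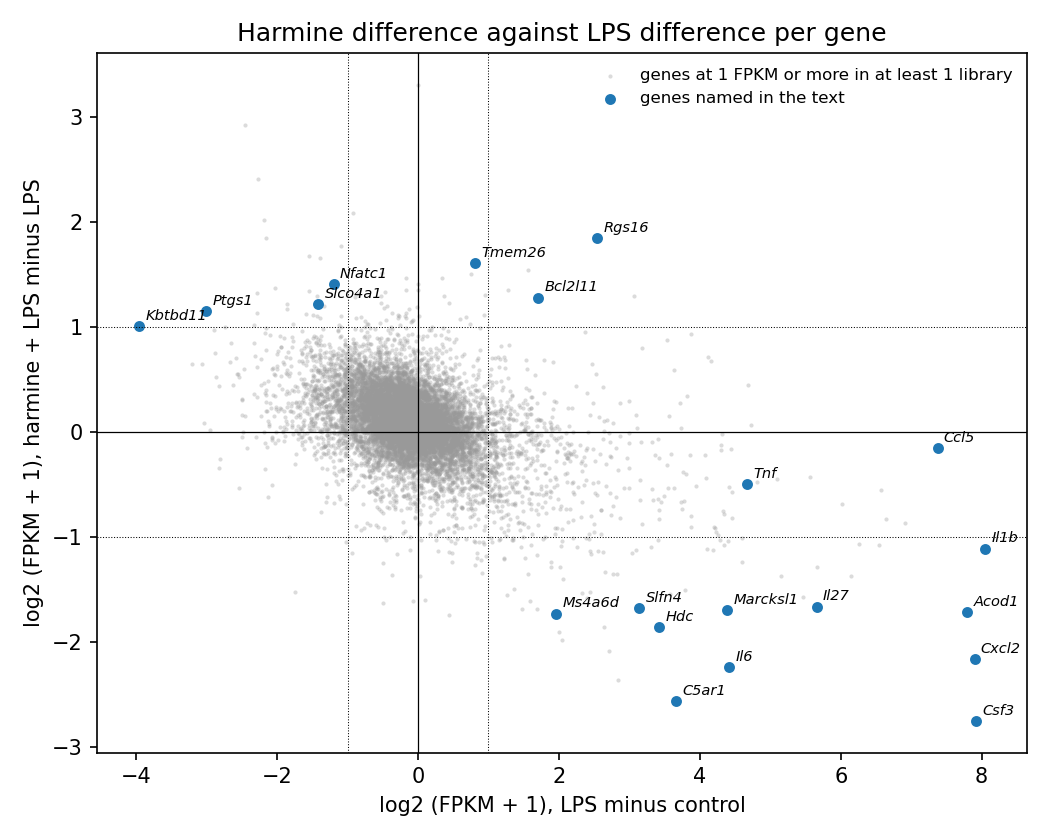
Each point is 1 of the compared genes, with its log2(FPKM + 1) difference between LPS and control on the horizontal axis and between harmine plus LPS and LPS on the vertical axis; dotted lines mark 2-fold. Csf3, Cxcl2 and Il6 lie at the lower right and Rgs16 and Bcl2l11 at the upper right; the LPS library enters both axes, which alone gives a negative correlation (-0.158 in simulated libraries, -0.453 observed).

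The last comparison set harmine plus LPS against control. The inflammatory state remained far from control: 15 of 18 cytokines, 11 of 16 chemokines, 39 of 43 interferon response genes and 18 of 21 NF-kB targets were 2-fold or more higher. In all, 627 genes were higher and 593 lower, with a median over all genes of -0.02 log2. Ccl5 was 278-fold (178 to 476) higher than control and Il1b 268-fold (179.9 to 398), followed by Acod1, Ptgs2 (6.05 log2), Il1a (6.02), Ccl22 (5.82), Cxcl2 (5.73), Ccl3 (5.47), Ccl4 (5.33) and Ccl2 (5.20). Il6, at 0 counts in control, was at least 47.6-fold higher against the same floor, Tnf differed by 4.17 log2 and Nos2 by 3.86.

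Among the lower genes, Lyl1, a haematopoietic transcription factor, stood at 73.9, 11.8 and 7.87 FPKM, and the fractalkine receptor Cx3cr1 at 91.3 FPKM in control and 12.1 with harmine plus LPS, 7.58-fold (7.06 to 8.14) below control. Kbtbd11 differed by -2.95 log2, Susd3 by -2.94, Klhl6 by -2.59, Tlr13 by -2.58, Tk1 by -2.56, Arhgap45 by -2.54 and Plau by -2.42. The immunoglobulin joining segment Ighj1 differed by -2.75 log2, from only 262 deposited counts in control. Replication and G1/S genes stayed below control, with 5 of 28 members 2-fold or more lower (median -0.70 log2), and G2/M genes with 1 of 26 (median -0.38). Macrophage identity genes had 5 of 17 members lower and none higher (median -0.49 log2, percentile 0.03), including Lyz2 at 967, 525 and 283 FPKM and Fcgr1 at 27.2, 13.8 and 5.67 FPKM. NRF2 targets had a median of -0.53 log2. Col1a1, Krt8 and the intestinal markers stood above control here too, by 1.54 and 1.68 log2 and, for the summed FPKM of the intestinal markers, 3.53-fold.

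The LPS and the harmine plus LPS library shared 497 of their 706 and 627 genes higher than control, and 469 of their 880 and 593 lower genes. The differences from control correlated across genes at r = 0.900, with a covariance of 0.495. Simulated noise with neither an LPS nor a harmine effect, sharing only the control, gave 0.500 and 0.0339. That 0.500 is fixed by the shared control, since the noise had equal spread in each library. The correlation is therefore given as a description, and the simulated value does not test it. Both lists and both differences rest on the same control library, which cannot be split, so the overlap is given without a chance value.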

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

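The tests in this part were chosen after the results were seen. Igsf6 stood above control with LPS (0.44 log2) and below it with harmine plus LPS (-1.31 log2); the difference between the conditions was not tested. Slc6a12 stood below control with LPS (-0.89 log2) and above it with harmine plus LPS (0.39 log2), also untested. Both were singled out because the named gene lay on opposite sides of control in the treated libraries, by at least 0.32 log2 each time.

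Transcripts of tissues that a macrophage line is not known to express stood higher in both LPS libraries than in control. By summed counts, scaled between libraries by the ratio of count to FPKM, keratinocyte markers were 5.10-fold higher with LPS (95% counting interval 4.13 to 6.32), intestinal markers 3.60-fold (3.38 to 3.83) and neuron and glia markers 4.50-fold (3.83 to 5.29); with harmine plus LPS the ratios to control were 6.52, 3.67 and 3.43. By summed FPKM, which weighs long genes less, they were 4.85, 3.48 and 4.06 with LPS and 6.19, 3.53 and 3.34 with harmine plus LPS. Other lists went elsewhere: immunoglobulin markers were at 0.425 and skeletal muscle markers at 0.359 of control with LPS, endothelium at 1.16, fibroblast at 1.98, liver at 1.72 and testis at 0.734 by counts, where summed FPKM gave 0.502, 0.339, 1.15, 1.34, a level liver sum (2.18 FPKM in control, 2.22 with LPS) and 0.750, and exocrine pancreas was at or below 4 counts in every library. Of the immunoglobulin sum (163.8, 82.3 and 78.6 FPKM), Ighm made up 152.1, 44.6 and 35.8 FPKM in control, LPS and harmine plus LPS, whereas Igkc stood at 7.05, 23.5 and 27.7 FPKM; the source of either was not tested. The marker lists were written after some such genes had been seen in these libraries, and leave those genes out; the genes named here were picked after seeing their values.

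If RNA of other tissues had entered the LPS libraries in general, most marker lists should have been higher; 3 of the 9 lists that reached the floor were, so this test leaves a general admixture open. Deeper sequencing of the LPS libraries is argued against: at one total of read pairs, the LPS library still detected 1.0651 times as many genes as control (21283 against 19982), and it had fewer counts to begin with. A single source of intestinal RNA keeps its genes in 1 ratio between libraries. Of 15 intestinal markers with at least 12 counts in each library, 14 were 2-fold or more higher with LPS, with a median of 3.66-fold, and their spread (0.17 log2, robust SD) lay at percentile 0.33 of 10000 random sets of genes that were 2-fold or more higher with LPS at like levels (median 0.68). Reg3b stood at 20.4, 74.7 and 70.4 FPKM, Fabp2 at 15.0, 45.5 and 50.2 and Zg16 at 3.39, 12.4 and 12.3; intestinal RNA in all 3 libraries, more of it in the LPS libraries, may therefore account for these genes, while an effect of the treatment on them stays open with 1 library per group.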

How the results depend on the processing

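The alternatives limited by counting intervals and without other-tissue markers were chosen after seeing the data. Counts of 2-fold genes are given as higher and lower for LPS against control, harmine plus LPS against LPS, and harmine plus LPS against control; as deposited they were 706 and 880, 81 and 114, 627 and 593. A pseudocount of 0.1 FPKM gave 1068 and 1482, 350 and 226, 1068 and 975, a pseudocount of 5 FPKM 347 and 291, 15 and 38, 296 and 188, and TPM rescaling, which enlarges every value about equally and so shrinks the pseudocount and the filter beside it, 1327 and 1405, 345 and 254, 1359 and 959. A 1.5-fold threshold gave 1426 and 2356, 646 and 408, 1500 and 1652 and a 4-fold threshold 225 and 86, 5 and 6, 170 and 47, by construction more and fewer genes. A filter at 5 FPKM left 47 genes higher with harmine. All other counts of 2-fold genes were within 1.5 times the values as deposited: median-of-ratios rescaling gave 752 and 796, 55 and 165, 562 and 691, upper-quartile rescaling 764 and 766, 70 and 131, 621 and 591, and genes whose counting interval left out a ratio of 1 numbered 691 and 864, 75 and 112, 610 and 584. Leaving out the filter changes no 2-fold count by construction, since a pseudocount of 1 FPKM keeps genes under 1 FPKM within 2-fold. For reversal, given as higher genes that were lower and higher with harmine, lower genes that were higher and lower, and both recovered shares, the values as deposited were 200 and 28, 193 and 11, and 14.3% and 22.6%. They were 298 and 79, 532 and 34, and 10.5% and 29.2% at a pseudocount of 0.1 FPKM, 97 and 11, 29 and 2, and 15.9% and 17.8% at 5 FPKM, 146 and 24, 160 and 11, and 12.8% and 25.0% with the 5 FPKM filter, 273 and 14, 110 and 13, and 21.3% and 15.6% after median-of-ratios rescaling, 381 and 55, 429 and 18, and 15.1% and 25.9% after TPM rescaling, 240 and 22, 143 and 10, and 17.9% and 19.5% after upper-quartile rescaling, 98 and 10, 32 and 1, and 14.9% and 17.2% for genes 4-fold apart with LPS and 77 and 5, 28 and 2, and 14.3% and 22.6% for 2-fold the other way. Where no construction is named, the cause was not tested. Of 783 list medians under the alternatives, 38 changed sign; the 46 medians at 0.32 log2 or more in size changed it in 2 cases, both of 1 median, that of the 5 replication-dependent histones in harmine plus LPS against control (0.0219 without the filter and 0.18 after TPM rescaling, from -0.40). Rescaling turned the sign of 2 list medians for LPS against control, 7 for harmine plus LPS against LPS and 4 against control, none of that size but the histones. Depth limits genes with few counts: a count of 0 allows up to 3 read pairs, and 39 of the 81 higher and 28 of the 114 lower genes with harmine had under 5 FPKM in both libraries.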

Other observations

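The scan of KEGG pathways and the tests of common damping, scaling and chance were chosen after the results were seen. The test of AU-rich elements was fixed first. Most disease pathways of KEGG were left out of the scan by their number. Several DNA repair pathways were lower with LPS and higher with harmine. So were the DNA replication pathway (35 genes, medians -0.98 and 0.49 log2) and the cell cycle pathway (112 genes, -0.52 and 0.31). Whether the repair genes differed apart from the replication and mitosis genes was not tested. Of 39 compared genes of homologous recombination, none of which were in the fixed lists, 22 were 1.5-fold or more lower with LPS (median -0.70 log2), and the median with harmine against LPS was 0.40. Base excision repair (33 genes) had medians of -0.66 and 0.31 log2 and the Fanconi anemia pathway (48 genes) -0.58 and 0.36, and 19 of 22 mismatch repair genes were 1.5-fold or more lower with LPS. Nucleotide excision repair (43 genes) had -0.23 log2 with LPS, within the middle 95% of random lists (percentile 9.55), and 0.29 with harmine. Fatty acid degradation (33 genes) had medians of -0.62 log2 with LPS and 0.03 with harmine, degradation of branched-chain amino acids (42 genes) -0.56 and 0.02, lysine degradation (46 genes, within the middle 95% with LPS) -0.20 and 0.16, and synthesis of unsaturated fatty acids (21 genes) -1.02 and 0.09, 14 of its genes being 1.5-fold or more lower with LPS. With harmine, each of these fatty acid and amino acid pathways lay within the middle 95% of random lists. Proteasome genes (44) had medians of 0.32 and -0.22 log2 (percentiles 100 and 0), but only 7 were 1.5-fold or more higher with LPS, and with harmine 1 was lower and 1 higher. Of 199 pathways, 40 lay above the middle 95% of random lists and 35 below it with LPS, and 12 and 57 with harmine, where about 4.98 fall in each tail by chance; pathways share genes.

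Among lists not described so far, apoptosis regulators had 8 of 21 members 2-fold or more higher with LPS and 2 lower, with the survival gene Bcl2a1d at 34.2, 544 and 381 FPKM and the death receptor Fas 3.00 log2 higher with LPS; with harmine against LPS Bid differed by 0.52 log2. MHC class I presentation had 3 of 16 members higher with LPS (median 0.40 log2, -0.30 with harmine against LPS), the peptide transporter Tap1 at 3.17, 14.7 and 8.52 FPKM and Tapbp at 31.9, 94.1 and 82.6 FPKM. Heat shock genes had medians of 0.49 and -0.18 log2, with Hspa8 at 614, 1221 and 853 FPKM. Ribosome biogenesis and MYC targets had a median of 0.30 log2 with LPS, none of 22 being 1.5-fold or more lower, with Odc1, the first enzyme of polyamine synthesis, at 89.2, 658 and 642 FPKM. Costimulation genes had a median of -0.11 log2 with harmine, none of 7 passing 2-fold. Lysosome and autophagy genes had medians of 0.05 and -0.09 log2, p53 targets -0.24 and 0.16, with 4 higher and 2 lower with LPS, alternative activation genes (5 compared) 0.29 and -0.14, and replication-dependent histones (5 compared) -0.67 and 0.27. Glycolysis and HIF-1 targets had -0.09 and 0.03 log2 and ribosomal proteins -0.27 and 0.01; with harmine the sign of both changes under rescaling, as does that of oxidative phosphorylation (0.05), cholesterol (0.09), LXR target (0.09), ribosome biogenesis (0.05) and apoptosis genes (0.04), and with LPS that of NRF2 targets (-0.02) and harmine targets (-0.02), 4 of the latter being 2-fold or more lower, Dyrk3 (-1.79), Nfatc2 (-1.28), Nfatc1 (-1.20) and Rcan3 (-1.18). ATF4 and unfolded protein response genes had 0.32 log2 and osteoclast genes 0.14 with LPS, and mitochondrial transcripts -0.29. Only 2 targets of the aryl hydrocarbon receptor reached 1 FPKM, Tiparp at 5.64, 10.0 and 8.10 FPKM and Lpar6 at 2.15, 1.89 and 1.76 FPKM. Of the lymphocyte, neutrophil and red cell markers only globins did, Hbb-bs at 3.50, 2.94 and 7.49 FPKM and Hba-a1 at 3.13, 2.78 and 4.19 FPKM, with a list median of -0.13 log2 with LPS and 0.92 with harmine.

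The 225 genes 4-fold or more higher with LPS had a median of -0.51 log2 with harmine against LPS; 53 were 2-fold or more lower. Had harmine damped the LPS response by one common share, the genes would lie around one line. Their spread around it was 2.769 times that of genes LPS moved by under 1.2-fold at the same level (0.54 against 0.20 log2). Choosing the latter for a small LPS difference may itself narrow their spread. With 1 library each, it is also unknown how much LPS-raised genes vary between cultures, so this test cannot decide on a common damping. This test and the next were run earlier on the 185 of these genes at 10 FPKM or more with LPS, where the values are 2.57 and -0.613 log2. Scaling between libraries is argued against, since after median-of-ratios rescaling the median was -0.641 log2. Chance in the shared LPS library, simulated independently for each gene, gave at most 33 genes lower, against 200 observed. A candidate explanation is that harmine lowers some LPS-raised genes, such as Csf3, Il6 and Cxcl2, more than others, such as Ccl5 and Nos2. Csf3 and Cxcl2 were picked by this same difference, so they illustrate it and do not test it. With 1 library each, differences between cultures stay open. Without a library given harmine alone, an effect of harmine that does not depend on LPS stays open too.

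The replication and G1/S list stood part of the way back to control with harmine (0.551 log2 against LPS). Simulated libraries with no harmine effect reached at most 0.17, so chance acting on each gene separately does not account for it. The simulation drew noise independently for each gene, so it cannot decide on a chance deviation shared by the genes of the list. After median-of-ratios rescaling the list was at 0.432, so scaling does not account for it. Harmine may have offset part of the lower proliferation-gene level of the LPS library, but a difference in cell density or cycle between the cultures was not tested and stays open.

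One hypothesis for which LPS-raised genes harmine lowered was AU-rich elements, the 3' UTR motifs through which many cytokine mRNAs are destabilised. Of 706 genes higher with LPS, 603 had an annotated 3' UTR, and 66 of these held the nonamer TTATTTATT. Their median with harmine against LPS was -0.25 log2, and -0.24 for the 537 genes without it, at percentile 70.47 of sets matched on the LPS difference. The nonamer did not mark the genes that were lower with harmine.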
